A study of Homo sapiens with 10 samples.

How the data were processed

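RNA was measured in 10 libraries of the KYSE150 esophageal squamous carcinoma line, 2 for each of 5 transfections: wild-type caspase-8 (WT) and the mutants M4, M6, M10 and M13. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented, copied with random hexamers and read as single-end 50-base reads on a BGISEQ-500 instrument. The protocol names no step that keeps strand. The deposited files give 1 FPKM value per gene and library (fragments per kilobase of transcript and 1e6 mapped fragments, a unit named per the file headers), over 57730 genes identified by Ensembl ID and symbol. The submitters' processing notes list HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and build hg38, with no role or order; how the authors made the FPKM values from them is not given in the sources used here. FPKM divides each gene by the total of its library, so a large change in a few genes shifts all others, and values of genes with near-identical copies depend on how reads were divided.

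The groups, tests, covariates, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan assumed counts and a count model. The files hold FPKM, so the test it named for this case was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), with all 10 libraries in 1 fit (5 residual degrees of freedom, prior 3.13), the groups as the only term and Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 13244 of the 26993 listed above 0 in at least 1 library. Genes of the Y chromosome, their pseudoautosomal copies, XIST and TSIX were left out (521 entries). Errors of log2 fold changes are standard errors of the fit; FPKM values are means ± SD over 2 libraries. No library pair held identical values. Comparisons were each mutant against WT, the mean of the 4 mutants against WT, each pair of mutants, any difference among the 5 groups, and genes called in all 4 mutants in 1 direction. M10 against the mean of M4, M6 and M13 was added after the data were seen and fitted on the 8 mutant libraries alone (4 residual degrees of freedom). In each fit limma pools part of the spread over genes. The prior degrees of freedom of the fit on mutant libraries were not recorded. With 4 residual degrees of freedom, its smallest p-values rest largely on that pooled spread.

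Gene lists were tested with camera (preset correlation 0.01) with Benjamini-Hochberg adjustment over 30 pathway lists, with the correlation estimated from the residuals as an alternative, and with fry, whose test asks whether the genes of a list move on balance 1 way. The pathway lists were extrinsic apoptosis, intrinsic apoptosis and the BCL2 family, necroptosis and pyroptosis, NF-kappaB feedback and target genes, inflammatory cytokines and chemokines, type I interferon response, antigen presentation and interferon gamma, immediate early and AP-1, p53 targets, integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2 targets, hypoxia and glycolysis, cholesterol biosynthesis, fatty acid synthesis and lipid storage, S phase, G2 and mitosis, MYC targets, ribosomal proteins, oxidative phosphorylation, TGF-beta targets, epithelial to mesenchymal transition, epithelial junctions, squamous basal identity, squamous differentiation, metalloproteinases, DNA damage repair, autophagy and lysosome, and metallothioneins. Lists chosen to reflect RNA quality (mitochondrially encoded transcripts, replication-dependent histones, nuclear retained long RNAs) and markers of other cells (fibroblast, endothelial, leukocyte, embryonic kidney or hepatic culture) were described without that test. A member rose or fell when its own adjusted p over all genes passed.

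Genes were named by rule. For each mutant against WT these were, among genes past the threshold with a mean FPKM of at least 5 in the higher group (the plan had a threshold on counts) and both mutant libraries on the same side of both WT libraries, the 10 highest and 10 lowest fold changes. CASP8 and up to 4 members of smallest p in each list described were added. For genes called in all 4 mutants the rule took the 10 per direction with the largest smallest change, and for the mean of the mutants and each mutant pair the 4 highest and 4 lowest. Where fewer than 5 genes passed, the 5 of smallest p were taken. A few genes that the rule selects are not reported here. Coordinates are of GENCODE v29 on GRCh38, matched by gene ID. GC content and length come from its transcripts and were available for 12895 tested genes.

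The test was tried on simulated data with 50 genes changed at each of 4 sizes among 13244. With equal noise in all groups, M4 against WT recovered 66%, 94%, 100% and 96% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 11 false among 189 calls; with noise as measured per group it recovered 58%, 76%, 98% and 96%, with 1055 false among 1219. With weights for WT and mutant libraries these shares were 4%, 28%, 72% and 88%, with 137 false among 233. For M10 against the mean of the other mutants, with noise as measured, they were 74%, 96%, 100% and 98%, with 12 false among 196. Total depth is unknown. Relative depth was read from the most common ratio of low FPKM values (under 0.5) to those of WT replicate 1, shared by 460 to 678 of 3430 to 3901 genes compared. Sums of FPKM per library ran from 851100 to 994260. They were 877708 and 866335 in M10 and 935559 to 946651 in the other mutant libraries.

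Alternatives tried were a pseudocount of 0.1, no filter, a stricter filter at an FPKM of 5, a log2 fold change of at least 1, a block for the replicate number, only the 4 libraries of a comparison, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. For WT that assumption does not hold. The median absolute log2 difference between replicates was 0.438 in WT and 0.0674 to 0.0765 in the mutants. Calls and p-values from fits with 1 WT library therefore cannot show that a result is robust. Added after the data were seen were median-of-ratios and upper quartile scaling of FPKM, removal of each library's smooth trend on GC content and log length (natural splines, 5 degrees of freedom each, relative to the mean of all libraries), limma array weights with 1 weight for WT and 1 for mutant libraries, both together, and the mutant libraries alone. Neither scaling moved the median of all genes by over 0.1 in any comparison with WT or of M10 with the other mutants. With 2 libraries per group, no test for outlying samples and no regrouping of samples applied. Chance overlap through the shared WT libraries was simulated in 20 draws, once with independent noise and once with WT libraries deviating as wholes. The covariance of fold changes was also taken with a different WT library for each mutant of a pair. Count models were left out because the files hold no counts.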

Results

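The 10 libraries came from KYSE150, an established line of esophageal squamous cell carcinoma, and measured polyadenylated RNA by short-read sequencing. Cells had been transfected with wild-type caspase-8 (WT) or with 1 of 4 caspase-8 mutants named M4, M6, M10 and M13, with 2 libraries in each of the 5 groups. Caspase-8 is the initiator protease of death-receptor apoptosis, and it also restrains necroptosis and takes part in inflammatory signalling. The labels used here do not say which residues each mutant changes. Nothing in the labels says that the replicates were separate cultures, so the p-values of single genes measure only the spread between these samples. Limma pools part of that spread over genes, so very small p-values do not come from 2 libraries per group alone. Camera with the preset correlation takes genes as nearly independent, so its p-values measure spread across genes and not between samples. The files hold FPKM values without counts, so total depth is unknown. From the steps between low FPKM values, relative depth was 0.887 in WT replicate 2 and 0.840 to 0.989 in the mutant libraries, with WT replicate 1 set to 1. Between 12416 and 12596 genes reached an FPKM of 1 in each library.

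The 8 mutant libraries resembled each other across genes (Pearson r on the log2 scale 0.990 to 0.997), whereas the WT libraries stood apart from them and from each other. WT replicate 1 correlated with the mutant libraries at 0.898 to 0.907, WT replicate 2 at 0.804 to 0.820, and the WT libraries with each other at 0.963. Genes are not independent replicates, and these values only describe the libraries. The median absolute log2 difference between replicates was 0.438 in WT, against 0.0674 in M4, 0.0755 in M6, 0.0707 in M10 and 0.0765 in M13. Transcript GC content and length together accounted for 22.6% of the variance of the difference between WT replicate 1 and the mutant mean, for 49.6% in WT replicate 2, and for 1.25% to 11.2% in the mutant libraries. The 1290 genes of lowest GC content (27.8% to 40.2%) had a median log2 difference from the mutant mean of -0.82 in WT replicate 1 and -1.86 in WT replicate 2, and the 1290 of highest GC content (62.3% to 75.8%) had 0.36 and 0.88. For most lists that passed, the median after removal of this trend (corrected) is therefore given too, and the adjusted p with both the correction and an estimated correlation (with both).

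**Figure D1:**
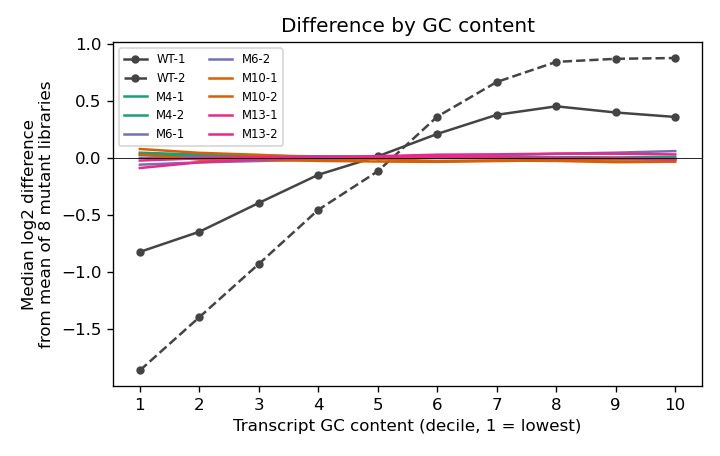
Median log2 difference in FPKM of each library from the mean of the 8 mutant libraries (vertical axis) in 10 bins of genes ordered by transcript GC content (horizontal axis), 1 line per library. The WT lines run from -0.82 and -1.86 in the lowest bin to 0.36 and 0.88 in the highest, and the mutant lines stay near 0.

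CASP8 mRNA itself (ENSG00000064012, chromosome 2 from 201233443 to 201287711, GRCh38) separated the groups first. It measured 131 ± 0.576 FPKM in WT (mean ± SD, n = 2), 4912 ± 23.9 in M4, 6927 ± 128 in M6 and 5536 ± 87.2 in M13, but only 463 ± 16.6 in M10. Against WT it rose in every mutant, with log2 fold changes of 5.22 ± 0.07 (SE) in M4, 5.72 ± 0.07 in M6, 5.39 ± 0.07 in M13 and 1.81 ± 0.07 in M10 (limma adjusted p = 8.3e-09, 4.0e-09, 6.4e-09 and 2.0e-06). In M10 it lay below M4 with a log2 fold change of -3.41 (adjusted p = 2.6e-07) and below M6 with -3.90 (adjusted p = 8.8e-08). M6 and M4 differed by 0.50 ± 0.07, which did not pass in the fit of all 10 libraries (adjusted p = 0.339) and passed in the 8 mutant libraries alone (adjusted p = 6.2e-08). No untransfected library was analysed here and transgene reads cannot be told from endogenous ones, so these values do not show how much caspase-8 the WT transfection added. The comparisons below contrast libraries that differ in the mutation and in CASP8 level together.

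**Figure D2:**
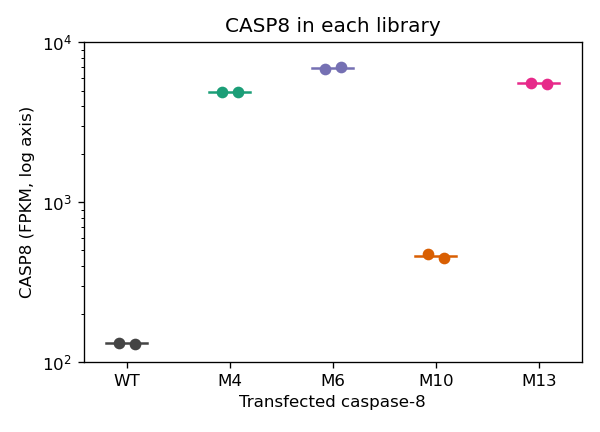
CASP8 in each library, in FPKM on a log axis, by transfected caspase-8. Points are libraries and lines are the means of 2, at 131 in WT, 4912 in M4, 6927 in M6, 463 in M10 and 5536 in M13.

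Each mutant was compared with the libraries labelled WT, which differ from it in CASP8 level as well as in the caspase-8 transfected. ANKRD37, IFIT2, CCL5 and MALAT1 were among the 10 genes with the largest increases shared by all 4 mutants. ANKRD37 (ENSG00000186352, chromosome 4 from 185396021 to 185400628), an ankyrin-repeat gene induced through hypoxia-inducible factor, stood at 1.79 ± 0.565 FPKM in WT and 194 ± 1.17 in M4, a log2 fold change of 6.14 ± 0.14, adjusted p = 1.5e-07. It gave 5.90, 5.11 and 6.08 in M6, M10 and M13. IFIT2 (ENSG00000119922, chromosome 10 from 89283694 to 89309276), an interferon-induced antiviral protein, rose from 2.59 ± 1.47 to 161 ± 5.47 FPKM in M4 (5.55 ± 0.23, adjusted p = 2.7e-06). The chemokine CCL5 (ENSG00000161570), a recruiter of T cells, went from 2.17 ± 0.606 to 134 ± 0.656 (5.43 ± 0.13, adjusted p = 2.6e-07). The antiviral helicase DDX60 (5.12 ± 0.40, adjusted p = 3.0e-05), IFIT3 (4.92 ± 0.21, adjusted p = 3.0e-06), and RSAD2 (4.57 ± 0.18, adjusted p = 1.9e-06) rose as well. So did the lipid-droplet protein HILPDA (4.98 ± 0.12, adjusted p = 2.4e-07), the arrestin-domain protein ARRDC3 (4.52 ± 0.31) and cyclin G2 (CCNG2, 4.48 ± 0.18). The nuclear long RNA MALAT1 (ENSG00000251562, chromosome 11 from 65497688 to 65506516) went from 16.4 ± 11.6 to 1089 ± 46.2 FPKM in M4 (6.14 ± 0.38, adjusted p = 1.2e-05), with 5.72 for the mean of the mutants. RN7SL2 (5.83 ± 0.26) and RN7SL1 (4.79 ± 0.29), RNAs of the signal recognition particle, share reads with near-identical copies and are uncertain. After the GC and length trend was removed, ANKRD37 gave 6.75, IFIT2 4.53, DDX60 3.74 and MALAT1 4.73 in M4.

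The genes that fell most against WT had varied functions. The serine kinase PSKH1 (ENSG00000159792, chromosome 16 from 67893272 to 67929678) fell in M4 from 55.9 ± 16.5 to 2.63 ± 0.0479 FPKM (-3.94 ± 0.19, adjusted p = 4.4e-06). B3GALT6, a galactosyltransferase of the proteoglycan linker region, fell from 41.8 ± 9.27 to 2.56 ± 0.248 (-3.57 ± 0.17, adjusted p = 4.9e-06). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell to 15.4 ± 1.398 from 168 ± 43.4 FPKM (-3.35 ± 0.18, adjusted p = 7.1e-06). AARS, the alanyl-tRNA synthetase (-2.84 ± 0.13, adjusted p = 3.5e-06), PYCR1 of proline synthesis (-2.74 ± 0.18, adjusted p = 1.6e-05), and the GDP-fucose transporter SLC35C1 (-3.27 ± 0.19, adjusted p = 1.0e-05) fell in M4. So did NCOA5 (-3.18 ± 0.14), PPP1R10 (-3.08 ± 0.15), ZNF629 (-3.47 ± 0.25), PLEKHB1 (-3.21 ± 0.17) and PAPL (-3.02 ± 0.19). In M6 the naming rule also took CCDC71 (-3.20 ± 0.18), SLC35F6 (-3.15 ± 0.14) and ZNF747 (-3.13 ± 0.21). In M10 it also took the tRNA methyltransferase METTL1 (-2.78 ± 0.22) and the adaptor LAT2 (-2.77 ± 0.18), and TOMM40L gave -3.09 ± 0.22 in M13. The rule ranks genes within each mutant, so these names do not show a difference between mutants. CTBP1-AS2 (-3.08 ± 0.22 in M4) overlaps its sense gene with strand not stated, and FAM86A (-2.81 ± 0.20 in M10) has near-identical copies, so both are uncertain. Several of these transcripts are GC-rich, and the corrected log2 fold changes in M4 were -3.35 for PSKH1, -2.99 for B3GALT6 and -2.71 for PCK2.

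In all, limma called 9697 of 13244 genes in M4 (4966 higher, 4731 lower), 9563 in M6 (4899 and 4664), 9676 in M10 (4867 and 4809) and 9616 in M13 (4930 and 4686) at an adjusted p of 0.05. The mean of the 4 mutants gave 10475, and 9077 genes differed among the 5 groups. In all 4 mutants 8412 genes were called in the same direction (4268 higher, 4144 lower), led by MALAT1, DDX60 and ANKRD37 upward and by PSKH1, PLEKHB1 and B3GALT6 downward. These counts cannot be read as numbers of genes altered by the mutations, and the share of false calls among them was not measured. In simulated data with the spread measured in each group and 50 genes changed at each of 4 sizes, 1055 of 1219 calls in M4 against WT (86.5%) were false. With 1 weight for WT and 1 for mutant libraries the number was 137 of 233 (58.8%). These shares hold only for so few changed genes. In the measured data such weights left 5723, 5418, 5654 and 5540 genes called in M4, M6, M10 and M13, and 4756 in all 4. After the GC and length correction 6737 of the 9471 M4 calls that had a value kept their call and direction and 474 were called the other way. For M10 these were 6640 of 9450 and 529. The same WT libraries entered each comparison. With no effect simulated, 783 genes (mean of 20 draws) were called in all 4 mutants when noise was independent, and 1507.7 (maximum 7772) when the WT libraries deviated as wholes; independent lists would share 465. The covariance of the fold changes between mutants was 1.22, against 0.103 and 0.0561 (maximum 0.190) in those simulations. With a different WT library for each of the 2 mutants it was 1.13 (1.08 to 1.17 over pairs), and 0.717 after the correction, so the shared libraries alone did not give it, while any deviation common to both WT libraries stays in it.

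Genes of the hypoxia and glycolysis list rose in every mutant against WT. In M4, 19 of 22 measured members rose and 0 fell (20 and 0 adjusted over the list alone). The hypoxia median was 2.25, or 2.10 corrected (adjusted p = 9.1e-08, and adjusted p = 0.0288 with an estimated correlation, and 0.0133 with both). Adrenomedullin (ADM, ENSG00000148926, chromosome 11 from 10304680 to 10307397), a vasodilator peptide, rose from 28.7 ± 0.156 to 758 ± 0.61 FPKM (n = 2, 4.67 ± 0.08, adjusted p = 3.4e-08). The glucose transporter SLC2A3 went from 51.6 ± 1.17 to 665 ± 3.57 (3.66 ± 0.07, adjusted p = 1.0e-07). The glycolytic enzyme lactate dehydrogenase A (LDHA) went from 479 ± 24.0 to 2306 ± 12.7 (2.26 ± 0.07, adjusted p = 6.8e-07). The list median was 2.29 in M6, 2.43 in M10 and 2.45 in M13, and 2.10 to 2.31 over the 4 mutants after the GC and length correction. Without WT replicate 1 the M4 median was 2.38 and without WT replicate 2 it was 2.25. In M4 the mitochondrially encoded list had a median of -1.49 and the nuclear retained RNAs 1.52. The corrected values of these lists were -2.24 and 1.51.

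The type I interferon response, a set of antiviral genes switched on by interferon signalling, was the other list whose uncorrected call held with an estimated correlation in all 4 mutants. In M4, 25 of 33 measured members rose and 2 fell (25 and 2 adjusted over the list alone). The interferon median was 1.41, or 1.46 corrected (adjusted p = 3.4e-06, and adjusted p = 0.0288 with an estimated correlation, and 0.0133 with both). IFIT1 rose from 4.84 ± 1.42 to 154 ± 0.557 FPKM (4.75 ± 0.15, adjusted p = 7.6e-07). The viral RNA sensor OAS2 went from 0.398 ± 0.114 to 9.43 ± 0.0423 (2.90 ± 0.12, adjusted p = 2.2e-06). RSAD2, an antiviral enzyme, went from 0.916 ± 0.534 to 43.8 ± 1.003. IFIT1 gave 4.98 in M6. Medians were 1.63, 1.43 and 1.61 in M6, M10 and M13, and 1.26 to 1.90 over the 4 mutants after correction. The adjusted p with an estimated correlation was 0.0192, 0.0287 and 0.0194 for this list in M6, M10 and M13, where the hypoxia list gave 0.0192, 0.0287 and 0.0194. With both the correction and an estimated correlation, the mitosis (0.0127 to 0.0158), S phase (0.0139 to 0.0166), NF-kappaB (0.0149 to 0.0322), TGF-beta (0.0234 to 0.0399), basal squamous (0.0244 to 0.0325) and antigen presentation lists (0.0221 to 0.0322) passed in all 4 mutants too. The correction lowered the median absolute log2 difference between the WT replicates from 0.438 to 0.196. That difference enters the residuals from which the correlation is estimated. A deviation common to both WT libraries does not, so these passes do not exclude one. The mitochondrially encoded list, which was lower in the mutants, had medians of -1.49 to -1.11 in the same comparisons.

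**Figure D3:**
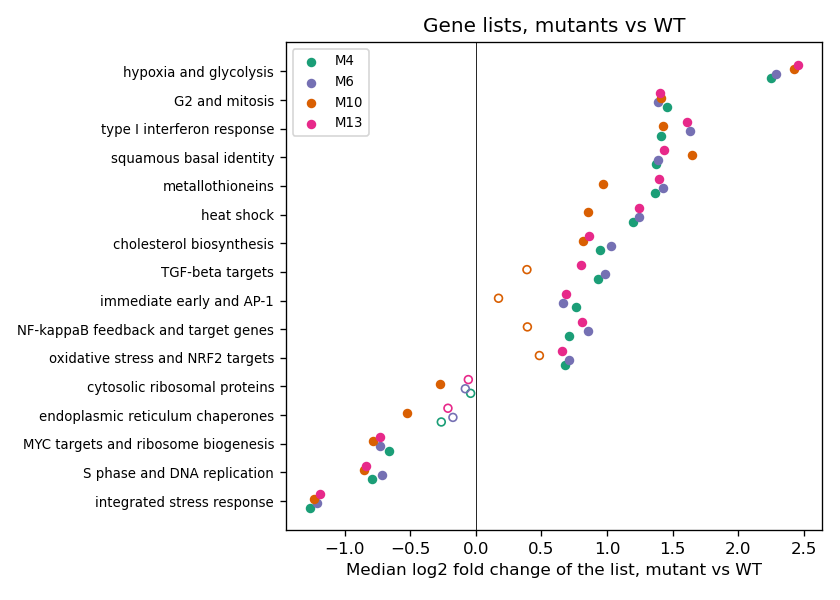
Median log2 fold change of each gene list (horizontal axis) in M4, M6, M10 and M13 against WT, for the lists that passed camera in at least 1 mutant; filled points passed at an adjusted p of 0.05 and open points did not. Hypoxia and glycolysis had the highest medians (2.25 to 2.45) and the integrated stress response the lowest (-1.26 to -1.19).

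Cell cycle genes moved in opposite directions. In M4, 25 of 30 measured members rose and 0 fell (25 and 0 adjusted over the list alone) in the G2 and mitosis list. The mitosis median was 1.46, or 0.95 corrected (adjusted p = 5.3e-06, but adjusted p = 0.204 with an estimated correlation, and 0.0133 with both). Securin (PTTG1, 1.44 ± 0.09, adjusted p = 1.1e-05), the mitotic kinesin KIF20A (1.41 ± 0.09, adjusted p = 1.5e-05) and cyclin B2 (CCNB2, 1.42 ± 0.09, adjusted p = 1.6e-05) rose. In the S phase and DNA replication list 0 of 26 measured members rose and 19 fell (0 and 19 adjusted over the list alone). The S phase median was -0.79, or -0.93 corrected (adjusted p = 0.000326, but adjusted p = 0.0954 with an estimated correlation, and 0.0166 with both). The flap endonuclease FEN1 fell from 142 ± 3.58 to 42.1 ± 1.08 FPKM (-1.73 ± 0.09, adjusted p = 7.5e-06). The replicative helicase subunit MCM3 fell from 521 ± 7.66 to 204 ± 3.92 (-1.35 ± 0.08, adjusted p = 1.2e-05), and its partner CDC45 from 38.3 ± 4.25 to 9.05 ± 1.404 (-1.97 ± 0.14, adjusted p = 2.1e-05). Over the 4 mutants the medians ran from 1.39 to 1.46 for mitosis and from -0.85 to -0.72 for S phase, and after correction from 0.75 to 0.95 and from -1.15 to -0.82. Replication-dependent histones, which normally lack a poly(A) tail, were higher in M4 (10 up and 0 down of 10, or 10 and 0 adjusted over the list alone; median 2.41, corrected 2.25), with HIST2H2BE at 4.48 ± 0.11, adjusted p = 2.9e-07. The histone list was chosen to reflect RNA quality and does not speak for a change in the cell cycle.

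Stress programmes diverged. The heat shock list rose in M4, where 15 of 16 measured members rose and 0 fell (15 and 0 adjusted over the list alone). The heat shock median was 1.19, or 0.93 corrected (adjusted p = 8.7e-05, but adjusted p = 0.0856 with an estimated correlation, and 0.0822 with both). The chaperone HSP90AB1 went from 706 ± 22.8 to 1386 ± 5.56 FPKM (0.97 ± 0.07, adjusted p = 2.1e-05). The co-chaperone DNAJB1 gave 1.19 ± 0.11, adjusted p = 5.9e-05, and HSPA1A, whose reads are shared with HSPA1B, 2.01 ± 0.10, adjusted p = 6.7e-06. The integrated stress response, the amino acid starvation programme driven by ATF4, fell: 4 of 22 measured members rose and 16 fell (4 and 16 adjusted over the list alone). The stress response median was -1.26, or -1.07 corrected (adjusted p = 0.000403, but adjusted p = 0.181 with an estimated correlation, and 0.0613 with both). With both, the call held in M6 (0.0493) and M10 (0.0427) and not in M13 (0.0608). Asparagine synthetase (ASNS) fell from 436 ± 13.4 to 69.8 ± 1.95 FPKM (-2.63 ± 0.10, adjusted p = 1.6e-06). The amino acid transporter SLC7A5 fell from 4334 ± 1159 to 720.2 ± 7.73 (-2.56 ± 0.15, adjusted p = 1.2e-05) and the glutathione-degrading CHAC1 to 4.04 ± 0.262 (-2.57 ± 0.14, adjusted p = 7.6e-06). Metallothioneins, which bind zinc and copper, rose: 5 of 5 measured members rose and 0 fell (5 and 0 adjusted over the list alone). The metallothionein median was 1.36, or 1.71 corrected (adjusted p = 0.00599, but adjusted p = 0.176 with an estimated correlation, and 0.0594 with both). The value with both was 0.0493 in M6, 0.0605 in M10 and 0.0543 in M13. MT1E stood at 1.36 ± 0.08 and MT1X at 1.79 ± 0.16, both near-identical to family members and uncertain. Over the 4 mutants the medians were 0.85 to 1.24 for heat shock, -1.26 to -1.19 for the integrated stress response and 0.97 to 1.43 for metallothioneins. The metallothionein call in M10 ended without WT replicate 1 (adjusted p = 0.0695). In M4 the mitochondrially encoded list had a median of -1.49 and the nuclear retained RNAs 1.52.

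Markers of the basal squamous layer rose in M4 (15 up and 1 down of 20, or 15 and 1 adjusted over the list alone). The basal squamous median was 1.37, or 1.11 corrected (adjusted p = 0.000275, but adjusted p = 0.0954 with an estimated correlation, and 0.0297 with both). The basal keratin KRT15 (ENSG00000171346, chromosome 17 from 41513743 to 41522529) rose from 32.9 ± 6.16 to 357 ± 2.28 FPKM (3.41 ± 0.12, adjusted p = 1.4e-06). The desmosomal protein PERP went from 131 ± 28.7 to 403 ± 2.31 (1.63 ± 0.13, adjusted p = 3.6e-05), with a corrected log2 fold change of 0.50. KRT14 (3.76 ± 0.18, adjusted p = 4.8e-06) shares reads with near-identical keratins. TGF-beta targets rose in M4 (13 up and 2 down of 20, or 13 and 2 adjusted over the list alone), among them the repressor BHLHE40 (3.09 ± 0.10, adjusted p = 6.8e-07). The TGF-beta median was 0.93, or 1.03 corrected (adjusted p = 0.0119, but adjusted p = 0.152 with an estimated correlation, and 0.0252 with both). The immediate early and AP-1 list rose too (13 up and 3 down of 21, or 14 and 3 adjusted over the list alone), with the zinc-finger factors KLF6 (2.91 ± 0.14, adjusted p = 4.6e-06) and KLF4 (1.78 ± 0.11, adjusted p = 1.2e-05). These factors are not AP-1 subunits, and the subunit FOSL1 was highest in WT. The AP-1 median was 0.76, or 1.15 corrected (adjusted p = 0.00647, but adjusted p = 0.405 with an estimated correlation, and 0.055 with both). With both, it passed in M6 (0.0377) and M13 (0.038). So did NF-kappaB feedback and target genes (14 up and 3 down of 22, or 14 and 4 adjusted over the list alone). The NF-kappaB median was 0.71, or 1.23 corrected (adjusted p = 0.0096, but adjusted p = 0.318 with an estimated correlation, and 0.0172 with both). Members that rose included the deubiquitinase TNFAIP3 (1.58 ± 0.09, adjusted p = 9.7e-06), the inhibitor NFKBIA (1.56 ± 0.14, adjusted p = 5.1e-05), NFKBIZ (2.23 ± 0.17) and superoxide dismutase SOD2 (2.79 ± 0.15, adjusted p = 7.0e-06). Over the 4 mutants the medians were 1.37 to 1.65 for basal squamous markers, 0.39 to 0.98 for TGF-beta, 0.17 to 0.76 for AP-1 and 0.39 to 0.86 for NF-kappaB. The lowest of the last 3, all in M10, became 0.38, 0.16 and 0.09 without WT replicate 1, and 0.63, 0.28 and 0.69 without WT replicate 2. Without WT replicate 1 the M4 calls of the TGF-beta (adjusted p = 0.0749), AP-1 (0.0884) and NF-kappaB lists (0.0828, with a median of 0.47) ended. The TGF-beta and AP-1 calls ended also in M6 (0.054 and 0.054) and M13 (0.0696 and 0.0622). In M10 these 3 lists did not pass (adjusted p = 0.125, 0.135 and 0.105). They passed after the correction (0.00101, 0.00136 and 0.000111). With the correction and an estimated correlation the AP-1 call was lost (adjusted p = 0.0399, 0.0706 and 0.0322). In the same comparisons nuclear retained RNAs, which were higher in the mutants, had medians of 1.02 to 1.52.

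Metabolic lists moved as well. NRF2 targets of the oxidative stress response rose in M4 (15 up and 3 down of 20, or 15 and 3 adjusted over the list alone). The NRF2 median was 0.68, or 0.47 corrected (adjusted p = 0.0209, but adjusted p = 0.217 with an estimated correlation, and 0.376 with both). Both subunits of the glutathione-synthesizing ligase rose, GCLM (1.86 ± 0.19, adjusted p = 8.9e-05, corrected 0.62) and GCLC (1.67 ± 0.18, adjusted p = 0.000115), while sulfiredoxin (SRXN1) fell (-0.91 ± 0.11, adjusted p = 0.000153). Cholesterol biosynthesis rose (12 up and 4 down of 21, or 12 and 4 adjusted over the list alone). The cholesterol median was 0.95, or 0.49 corrected (adjusted p = 0.0293, but adjusted p = 0.16 with an estimated correlation, and 0.115 with both). The sterol sensor INSIG1 went from 18.0 ± 1.78 to 169 ± 1.44 FPKM (3.16 ± 0.10, adjusted p = 7.2e-07) and the pathway enzyme HMGCS1 from 12.8 ± 3.70 to 119.6 ± 2.32 (3.16 ± 0.17, adjusted p = 6.8e-06). MYC targets and ribosome biogenesis fell (3 up and 13 down of 22, or 3 and 13 adjusted over the list alone), including ornithine decarboxylase (ODC1, -1.74 ± 0.13, adjusted p = 2.2e-05) and CAD of pyrimidine synthesis (-1.93 ± 0.16, adjusted p = 3.6e-05). The MYC median was -0.66, or -0.63 corrected (adjusted p = 0.0216, but adjusted p = 0.152 with an estimated correlation, and 0.0741 with both). With both, M6 (0.0729) and M13 (0.0638) did not pass and M10 did (0.0399). Without WT replicate 1 none of these 3 M4 calls remained (adjusted p = 0.139, 0.195 and 0.113). The same 3 ended in M6 (0.111, 0.116 and 0.0967) and M13 (0.147, 0.216 and 0.0971). In M10 the NRF2 list did not pass (adjusted p = 0.176) and the other calls ended (0.149 and 0.0696). Endoplasmic reticulum chaperones passed in M10 (3 up and 13 down of 20, or 4 and 13 adjusted over the list alone), with the disulfide isomerase PDIA4 at -1.73 ± 0.10, adjusted p = 1.7e-05. The chaperone median was -0.52, or -0.57 corrected (adjusted p = 0.0383, but adjusted p = 0.152 with an estimated correlation, and 0.0503 with both). That call ended without WT replicate 1 (adjusted p = 0.157). Cytosolic ribosomal proteins passed in M10 too (2 up and 16 down of 33, or 2 and 14 adjusted over the list alone). The ribosomal median was -0.27, or -0.07 corrected (adjusted p = 0.0383, but adjusted p = 0.505 with an estimated correlation, and 0.822 with both). It was -0.44 without WT replicate 1 and -0.14 without WT replicate 2. With the filter at an FPKM of 5 in 2 libraries neither the chaperone nor the ribosomal list passed in M10 (adjusted p = 0.0509 for each). The ribosomal call ended after the correction (median -0.07, adjusted p = 0.476) and without M10 replicate 2 (adjusted p = 0.0808). In M4 the mitochondrially encoded list had a median of -1.49 and the nuclear retained RNAs 1.52.

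No cell death list passed camera in M4, whereas fry passed intrinsic apoptosis (upward, adjusted p = 0.000203) and necroptosis and pyroptosis (upward, 0.0114) among 26 of the 30 lists. In the extrinsic apoptosis list of M4, 6 of 16 measured members rose and 7 fell (6 and 7 adjusted over the list alone), with an adjusted p of 0.725. Its median, -0.30 (-0.45 without WT replicate 1 and -0.14 without WT replicate 2), and test were negative and its mean, 0.05, positive. The death ligand TRAIL (TNFSF10) went up from 0.127 ± 0.179 to 3.72 ± 0.187 FPKM (2.08 ± 0.14, adjusted p = 1.6e-05). Its decoy receptor TNFRSF10D went from 16.8 ± 0.12 to 35.9 ± 0.901 (1.05 ± 0.10, adjusted p = 6.4e-05). The adaptor FADD, which recruits caspase-8, fell from 68.1 ± 16.7 to 15.3 ± 0.566 (-2.06 ± 0.17, adjusted p = 4.0e-05) and the kinase RIPK1 from 21.2 ± 1.83 to 7.33 ± 0.754 (-1.42 ± 0.12, adjusted p = 4.4e-05). Intrinsic apoptosis (10 up and 6 down of 19, or 10 and 6 adjusted over the list alone, adjusted p = 0.377), necroptosis and pyroptosis (5 up and 4 down of 12, or 5 and 4 adjusted over the list alone, adjusted p = 0.725) and p53 targets (7 up and 4 down of 18, or 7 and 4 adjusted over the list alone, adjusted p = 0.841) did not pass in M4. The p53 median was 0.03 as deposited and -0.01 with upper quartile scaling, -0.25 without WT replicate 1 and 0.26 without WT replicate 2. Inflammatory cytokines (6 up and 3 down of 15, or 6 and 3 adjusted over the list alone, adjusted p = 0.346) did not pass, although CCL5 rose. Nor did antigen presentation (10 up and 2 down of 20, or 10 and 2 adjusted over the list alone, adjusted p = 0.133), endoplasmic reticulum chaperones (4 up and 10 down of 20, or 4 and 10 adjusted over the list alone, adjusted p = 0.145) or epithelial junctions (13 up and 4 down of 23, or 13 and 4 adjusted over the list alone, adjusted p = 0.224). The last 3 of these passed after the correction (adjusted p = 7.7e-05, 0.0123 and 0.00575). With the correction and an estimated correlation only antigen presentation did (adjusted p = 0.0252, 0.0741 and 0.115). The remaining M4 results were 6 up and 7 down of 15, or 6 and 7 adjusted over the list alone for lipid synthesis and storage (adjusted p = 0.841) and 5 up and 7 down of 33, or 3 and 3 adjusted over the list alone for ribosomal proteins (0.841). There were 6 up and 12 down of 25, or 6 and 12 adjusted over the list alone for nuclear genes of oxidative phosphorylation (0.375) and 6 up and 13 down of 23, or 6 and 13 adjusted over the list alone for autophagy and lysosome (0.224). They were 6 up and 3 down of 11, or 7 and 3 adjusted over the list alone for epithelial to mesenchymal transition (0.253) and 7 up and 3 down of 13, or 7 and 3 adjusted over the list alone for squamous differentiation (0.32). Last came 8 up and 4 down of 17, or 8 and 4 adjusted over the list alone for metalloproteinases (0.338; 0.0265 corrected) and 6 up and 7 down of 20, or 6 and 7 adjusted over the list alone for DNA damage repair (0.709; 0.0337 corrected). Both corrected calls were lost with an estimated correlation (adjusted p = 0.151 and 0.108). The sign of the repair median, 0.08, hung on 1 WT library (0.40 without WT replicate 1, -0.42 without WT replicate 2), and its test was negative.

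The lists chosen to reflect RNA quality differed between WT and every mutant. No direct measure of RNA quality was at hand, so whether these lists reflect it was not tested. Mitochondrially encoded transcripts were lower in M4 (0 up and 12 down of 13, or 0 and 12 adjusted over the list alone; median -1.49), with MT-CYB at 3092 ± 981 FPKM in WT and 521 ± 31.2 in M4 (-2.53 ± 0.18, adjusted p = 2.3e-05). MT-ATP6 stood at 4000.4 ± 1218 and 825 ± 43.5 (-2.24 ± 0.17, adjusted p = 2.9e-05). Nuclear retained long RNAs were higher (8 up and 0 down of 9, or 8 and 0 adjusted over the list alone; median 1.52), led by MALAT1. WT replicate 2 lay beyond WT replicate 1 in both, by a median of 0.644 for the mitochondrial list and -0.356 for the nuclear RNAs. Replication-dependent histones, also chosen to reflect RNA quality, were higher in every mutant, with medians from 1.89 in M10 to 2.41 in M4. Markers of other cell types were too few among the tested genes to describe a group. Tested were 3 of 15 fibroblast markers (COL1A1 highest, at 7.52 FPKM in WT and 12.3 in M10) and 1 of 11 endothelial (EGFL7, 39.0 in WT). The others were 2 of 16 leukocyte (CD68, 212.7 in WT) and 2 of 13 kidney or hepatic culture markers (SERPINA1, 17.2 in WT, and LHX1, 7.68 in WT and 32.3 to 40.1 in the mutants).

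Among the mutants, M4, M6 and M13 were hard to separate. With all 10 libraries in 1 limma fit, 0 genes passed between M6 and M4, M13 and M4, or M13 and M6. Of 13244 genes 193, 176 and 231 had an unadjusted p under 0.05, where chance gives 662.2. The smallest p for M6 against M4 belonged to the pseudogenes CSPG4P10 and CSPG4P8, followed by CASP8, CCL3 and RP11-617D20.1. The pseudogenes share reads with copies and were listed at 0 in several libraries (log2 fold changes 2.04 and 2.07, adjusted p = 0.162 and 0.162). For M13 against M4 they belonged to the early growth response factor EGR1 (1.03 ± 0.15), HSPA6 (0.94 ± 0.17), CASP14, CRYAB and CTC-479C5.17. M13 against M6 gave CSPG4P10, CSPG4P8, EGR1 (0.82 ± 0.15), SYT8 and SENP3-EIF4A1. None passed in this fit. The WT spread enters these tests. In a fit of the 8 mutant libraries alone 227, 334 and 214 genes passed. All of the named genes except CTC-479C5.17 passed there, as they did with weights, with the 4 libraries compared and without either WT library. With weights 104, 91 and 104 did, and with the 4 libraries compared 272, 220 and 113. Without WT replicate 1 the counts were 227, 304 and 235, without WT replicate 2 225, 320 and 219, and 0 whichever mutant library was left out. M10 differed from each of the others, with 126 genes against M4 (43 higher, 83 lower; 87 and 101 with upper quartile scaling), 188 against M6 (68 and 120) and 98 between M13 and M10 (71 higher in M13, 27 lower). These counts became 5063, 5492 and 4796 in the mutant libraries alone. They were 5076, 5477 and 4818 without WT replicate 1, and 5075, 5498 and 4824 without WT replicate 2. They were at most 29 whichever mutant library was left out. The count was 1 for M10 against M4 without either M4 library or M10 replicate 2, 1 against M6 without either M6 library or M10 replicate 2, and 1 for M13 against M10 without M13 replicate 2. The genes of largest change in all 3 comparisons were CASP8, HSPA6 (-1.71 ± 0.17, adjusted p = 0.0107 against M4) and, upward in M10, ZSCAN31 (1.55 ± 0.18, adjusted p = 0.0133 against M4) and LRG1 (1.42 ± 0.19, adjusted p = 0.0239). Of these, CASP8 alone kept its call against M4 whichever library was left out.

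M10 was therefore set against the mean of M4, M6 and M13 in the mutant libraries alone, a comparison chosen after the data were seen. Cytokine, NF-kappaB target and heat shock genes were lower in M10. The AP-1 subunit FOSL1 (ENSG00000175592, chromosome 11 from 65892049 to 65900573) stood at 61.5 ± 2.41 FPKM in M10 (mean ± SD, n = 2) against 139 ± 0.122, 169 ± 0.151 and 152 ± 0.77 in M4, M6 and M13 (-1.30 ± 0.03, adjusted p = 6.3e-17). Its partner JUN (ENSG00000177606, chromosome 1 from 58780788 to 58784327) stood at 177 ± 3.14 against 374 ± 5.08, 380.1 ± 8.54 and 362 ± 9.02 (-1.07 ± 0.03, adjusted p = 1.2e-16). The chemokine CCL5 was 74.4 ± 3.05 in M10 against 134 ± 0.656, 193 ± 6.78 and 194 ± 2.998 (-1.19 ± 0.03, adjusted p = 2.9e-16). The neutrophil chemokine interleukin 8 (IL8) was 12.8 ± 0.797 against 31.2 ± 0.415, 34.1 ± 0.605 and 29 ± 0.0564 (-1.23 ± 0.06, adjusted p = 5.6e-13). By size the genes lowest in M10 were CASP8 (-3.63 ± 0.03), the inducible chaperone HSPA6 (-2.14 ± 0.11, reads shared with HSPA1 genes), the forkhead factor FOXD1 (-1.97 ± 0.62), MIR29B1 (-1.57 ± 0.07, read from its host locus) and the serpin SERPINB2 (-1.44 ± 0.10). Next came MYEOV (-1.44 ± 0.07), IGFN1 (-1.36 ± 0.09), FOSL1 and the cytokine IL24 (-1.30 ± 0.12). Higher in M10 were the zinc-finger gene ZSCAN31 (ENSG00000235109, chromosome 6 from 28324693 to 28356271; 19.7 ± 0.222 FPKM against 6.06 ± 0.55, 5.59 ± 0.427 and 6.02 ± 1.07; 1.59 ± 0.10, adjusted p = 6.6e-11), the secreted glycoprotein LRG1 (1.36 ± 0.08), the aldehyde dehydrogenase ALDH3B2 (1.16 ± 0.09) and EGR1 (1.11 ± 0.06). So were METTL7A (1.09 ± 0.08), the interferon-induced IFITM1 (1.08 ± 0.10), the keratinocyte caspase CASP14 (1.06 ± 0.05) and ZNF629 (1.06 ± 0.14). CEL (1.22 ± 0.08) and HIST2H4A (1.14 ± 0.22), higher too, are uncertain for near-identical copies. EGR1 was also higher in M13 than in M4 and M6, so M10 lay less far above M13 than above the mean. In all 6132 of 13244 genes passed, 2709 higher and 3423 lower (3162 and 3005 with upper quartile scaling). With a log2 fold change of at least 1 required, 47 passed, 17 higher and 30 lower. In simulated data with the measured spread 12 of 196 such calls (6.12%) were false, with as few genes changed. That noise was drawn gene by gene from the spread within the pairs of mutant libraries. It held no difference between transfections or in handling, so the share of false calls among the 6132 was not measured. After the GC and length correction 5263 of the 6007 calls with a value kept call and direction. FOXD1 lost its call without either M10 library (adjusted p = 0.0762 and 0.135).

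**Figure D4:**
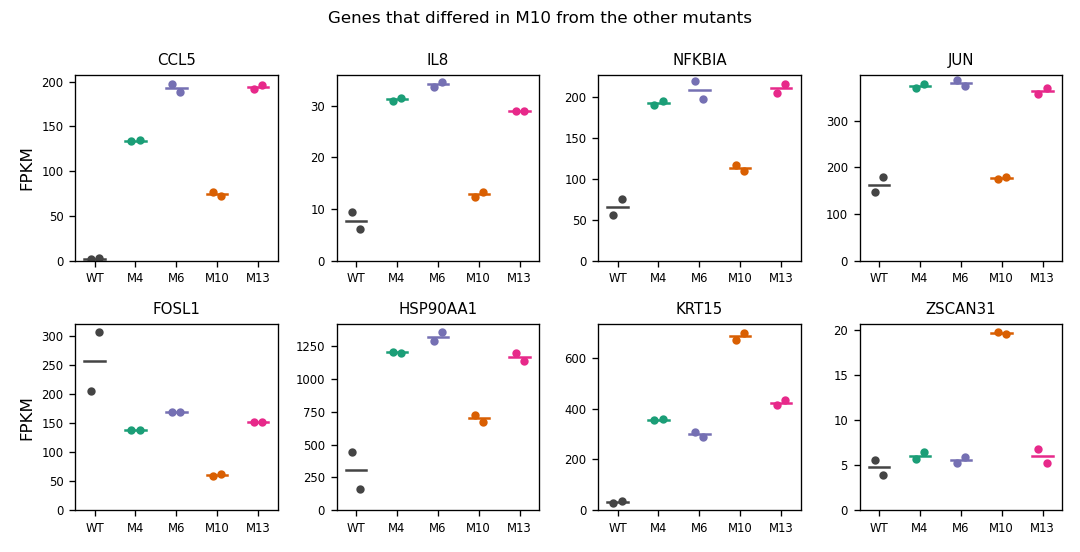
FPKM of 8 genes in each library (points) with group means (lines), vertical axes from 0. CCL5, IL8, NFKBIA, JUN, FOSL1 and HSP90AA1 were lower in M10 than in M4, M6 and M13, and KRT15 and ZSCAN31 higher; the WT libraries lie elsewhere, with FOSL1 highest in WT (257 ± 71.9).

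Gene lists followed in M10. Inflammatory cytokines and chemokines fell against the other mutants: 0 of 15 measured members rose and 14 fell (0 and 14 adjusted over the list alone). The cytokine median was -0.58, or -0.56 corrected (adjusted p = 2.9e-10, and adjusted p = 0.0352 with an estimated correlation, and 0.0328 with both). They included IL32 (-0.89 ± 0.05, adjusted p = 3.2e-11) and the pyrogen IL1B (-0.54 ± 0.03, adjusted p = 9.9e-11). Of the NF-kappaB feedback and target genes 1 of 22 measured members rose and 19 fell (1 and 20 adjusted over the list alone). The NF-kappaB target median was -0.43, or -0.42 corrected (adjusted p = 3.6e-10, and adjusted p = 0.0352 with an estimated correlation, and 0.0249 with both). The stress-response gene IER3 was 666 ± 6.77 FPKM in M10 and 1098 ± 1.28 in M4 (-0.70 ± 0.03, adjusted p = 8.3e-14). NFKBIA was 113 ± 5.53 and 192 ± 4.01 (-0.84 ± 0.04, adjusted p = 5.3e-13), SOD2 gave -0.58 ± 0.03, adjusted p = 3.8e-13 and the adhesion molecule ICAM1 -0.57 ± 0.03, adjusted p = 1.9e-12. In the heat shock list 0 of 16 measured members rose and 14 fell (0 and 14 adjusted over the list alone). The heat shock list median was -0.42, or -0.38 corrected (adjusted p = 2.4e-10, and adjusted p = 0.0352 with an estimated correlation, and 0.0249 with both). The stress-induced chaperone HSP90AA1 stood at 698 ± 34.1 FPKM against 1202 ± 5.42 in M4 (-0.81 ± 0.03, adjusted p = 4.6e-14). DNAJB1 gave -0.63 ± 0.03, and HSPA1A (-0.92 ± 0.04) and HSPA1B (-0.85 ± 0.03) share reads. In the immediate early and AP-1 list 3 of 21 measured members rose and 14 fell (3 and 14 adjusted over the list alone). The immediate early median was -0.40, or -0.45 corrected (adjusted p = 1.3e-05, but adjusted p = 0.136 with an estimated correlation, and 0.0738 with both). The phosphatase DUSP1 (-1.22 ± 0.05, adjusted p = 3.8e-14) and KLF6 (-0.61 ± 0.03) fell, and EGR1 rose. The lists chosen to reflect RNA quality moved too. Mitochondrially encoded transcripts were higher in M10 (11 up and 0 down of 13, or 11 and 0 adjusted over the list alone; median 0.52; MT-CO3 0.61 ± 0.03). Lower were nuclear retained RNAs (0 up and 9 down of 9, or 0 and 9 adjusted over the list alone; median -0.51; NEAT1 -0.93 ± 0.03, MALAT1 -0.62 ± 0.04) and histones (0 up and 7 down of 10, or 0 and 7 adjusted over the list alone; median -0.26). Across genes, the differences of M10 and of WT from M4, M6 and M13, each with separate reference libraries, correlated at 0.127 and 0.154 (0.249 and 0.270 corrected).

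Smaller shifts covered many lists, and none of the following calls held with an estimated correlation (adjusted p of at least 0.107, or 0.0738 with both). All cytosolic ribosomal protein genes measured were lower in M10: 0 of 33 measured members rose and 33 fell (0 and 33 adjusted over the list alone). The ribosomal protein median was -0.22, or -0.16 corrected (adjusted p = 3.3e-14, but adjusted p = 0.128 with an estimated correlation, and 0.0738 with both). RPL18 gave -0.29 ± 0.03, adjusted p = 3.4e-08, and 0 rose and all 33 fell also with upper quartile scaling. In the type I interferon list 5 of 33 measured members rose and 19 fell (5 and 19 adjusted over the list alone). The interferon list median was -0.21, or -0.21 corrected (adjusted p = 0.00116, but adjusted p = 0.118 with an estimated correlation, and 0.0738 with both). The ubiquitin-like ISG15 stood at 169 ± 2.29 FPKM against 306 ± 1.79 in M4 (adjusted p = 3.3e-15), and IFIT2 gave -0.90 ± 0.04. In the intrinsic apoptosis list 1 of 19 measured members rose and 10 fell (1 and 10 adjusted over the list alone). The intrinsic apoptosis median was -0.20, or -0.18 corrected (adjusted p = 0.00363, but adjusted p = 0.14 with an estimated correlation, and 0.101 with both). The BH3-only protein PMAIP1 stood at 82.7 ± 2.01 against 144 ± 1.59 FPKM in M4 (-0.92 ± 0.03, adjusted p = 5.3e-15), and its binding partner MCL1 gave -0.33 ± 0.03. Extrinsic apoptosis did not pass (5 up and 3 down of 16, or 6 and 3 adjusted over the list alone, adjusted p = 0.174). RIPK1 (0.56 ± 0.09, adjusted p = 3.2e-05), FADD (0.40 ± 0.08, adjusted p = 0.000245) and the TNF receptor TNFRSF1A (0.23 ± 0.04, adjusted p = 0.000132) rose, and the death receptor FAS fell (-0.35 ± 0.08, adjusted p = 0.000672, a call lost without M10 replicate 2 at 0.116). Necroptosis and pyroptosis did not pass either (3 up and 1 down of 12, or 3 and 1 adjusted over the list alone, adjusted p = 0.437), though the inflammasome protease CASP1 rose (0.58 ± 0.07, adjusted p = 7.9e-07). Metallothioneins fell (0 up and 5 down of 5, or 0 and 5 adjusted over the list alone), with MT2A at -0.78 ± 0.03. The metallothionein median was -0.30, or -0.33 corrected (adjusted p = 0.000824, but adjusted p = 0.118 with an estimated correlation, and 0.101 with both). Basal squamous markers passed upward (10 up and 4 down of 20, or 10 and 5 adjusted over the list alone), but not after the correction (adjusted p = 0.0892). The basal squamous median was 0.09, or 0.06 corrected (adjusted p = 0.0154, but adjusted p = 0.136 with an estimated correlation, and 0.305 with both). KRT15 (0.94 ± 0.03, adjusted p = 3.3e-15) and the cadherin FAT2 (0.54 ± 0.02) rose. The mitochondrially encoded median of 0.52 and the nuclear RNA median of -0.51 accompanied these shifts.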

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

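The tests in this part were all chosen after the result was seen. The difference between M10 and the mean of M4, M6 and M13 stood out, because a test of the difference between mutants itself passed in many genes: 6132 of 13244 genes passed in the 8 mutant libraries. Most of these changes were small: with a log2 fold change of at least 1 required, 47 genes passed.

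A trend with GC content and length is argued against as the whole cause, since 6202 genes passed after its removal and the cytokine list kept a median of -0.56. A difference in depth is argued against too: 0 of the M10 libraries lay outside the range of relative depth of the other mutant libraries. Their sums of FPKM, 877708 and 866335, did lie below those of the other mutant libraries (935559 to 946651). With upper quartile scaling 6167 genes passed. The level of caspase-8 mRNA, among the mutants lowest in M10, is a candidate explanation that cannot be told apart from the M10 mutation. In WT it was lower still (131 and 130 FPKM), and the WT libraries did not enter the shares that follow. Of the genes lower in M10, 57.4% were higher in M6, with the most CASP8, than in M4, against 37.7% of the genes higher in M10 and 47.3% of all genes, but the gap between the first 2 shares ran from 9.95 to 20.8 percentage points over 4 library pairings (17.5 after correction), and the lowest fell short of the 10 points required in every pairing, a requirement added after the first value was seen. RNA quality stays open as well: the mitochondrially encoded list was higher (0.52) and the nuclear RNAs lower (-0.51) in M10, the direction in which WT lies, so the mutation, the CASP8 level and handling of these libraries may each contribute.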

How the results depend on the processing

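The M10 comparison with the other mutants, GC and length correction, weights, both together, the added scalings and the mutant libraries alone were chosen after the data were seen. No named single-gene result reversed, but the GC and length correction turned the direction of 474, 440, 529 and 392 of all calls in M4, M6, M10 and M13 against WT. Of 187 single-gene results 123 kept direction and side of the threshold in every alternative; of their alternative values 3411 did, 132 lost the call and 82 gained it, and CASP8 against WT kept 84 of 84. The planned DESeq2, edgeR RLE and edgeR upper quartile fits were not run, because the files hold no counts. Where no cause is named below, the cause was not tested.

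Counts of mutants against WT and of M10 against the other mutants stayed within 1.5 times of the main ones under the pseudocount, filter, scaling, block and GC alternatives. A log2 fold change of at least 1, which by construction removes smaller changes, left 4886 (M4), 4671 (M6), 4798 (M10), 4769 (M13), 4749 (mean of mutants), 3901 (all 4 mutants), 43 (M10 against M4), 54 (M10 against M6), 31 (M13 against M10) and 47 (M10 against the mean of the others, 17 higher and 30 lower). Weights gave 5723, 5418, 5654, 5540, 5626 and 4756 for the first 6 of these.

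Counts between mutants depended on the fit. In the order M6-M4, M10-M4, M13-M4, M10-M6, M13-M6 and M13-M10, weights gave 104, 4988, 91, 5395, 104 and 4738; the 4 libraries compared alone 272, 5307, 220, 5528, 113 and 4716; the mutant libraries alone 227, 5063, 334, 5492, 214 and 4796; GC and length correction with weights 161, 5138, 98, 5417, 255 and 4611. GC and length correction alone gave 1832 (M10-M4), 1 (M13-M4), 2197 (M10-M6), 2 (M13-M6) and 1272 (M13-M10); log2(FPKM + 0.1) gave 1 (M6-M4), 75 (M10-M4), 1 (M13-M6) and 59 (M13-M10); no filter gave 46 (M10-M4), 115 (M10-M6) and 24 (M13-M10). Leaving out 1 library gave 0 to 227, 1 to 5076, 0 to 320, 1 to 5498, 0 to 235 and 1 to 4824 in the same order: the high values came without a WT library, the low ones without a mutant library.

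Replicate numbers gave no clear sign of pairing: 3 of 10 correlations of same-numbered deviations passed 0.1 (-0.241 to 0.240). The 3 were of WT with M4, M10 and M13 (0.101, 0.133 and 0.240), while WT with M6 gave -0.241. Between mutants they ran from -0.0824 to 0.0633. The values were not corrected for the GC trend of the WT libraries, so pairing with WT cannot be excluded. With a replicate block the counts were 9621, 9480, 9557 and 9534 for M4, M6, M10 and M13, 10402 for their mean, 8307 in all 4, 8846 among groups, 6048 for M10 against the other mutants, and 43 (M10-M4), 86 (M10-M6) and 17 (M13-M10).

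Of 30 lists 14, 14, 12 and 14 passed in M4, M6, M10 and M13. With an estimated correlation 2, 2, 2 and 2 did, and 3 instead of 21 for M10 against the other mutants; fry called 26, 26, 29 and 27; M10 with GC correction and weights 20; M10 with the filter at an FPKM of 5 in 2 libraries 10. Weights added NF-kappaB (adjusted p = 0.0294) and TGF-beta (0.0463) in M10 and antigen presentation in M13 (0.0454), and ended NRF2 in M13 (0.0513). Leaving out 1 library gave 8 to 17 in M4, 9 to 17 in M6, 8 to 18 in M10 and 9 to 17 in M13, lowest without WT replicate 1 and highest without WT replicate 2. FOXD1 lost its call in M6 and M10 without a filter, and FAS and HIST2H4A in M10 against the other mutants. Unknown depth and 2 libraries per group limit what these data can separate.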

Other observations

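In M10, further groups shifted against the mean of M4, M6 and M13. Lipid synthesis rose (6 up and 2 down of 15, or 6 and 2 adjusted over the list alone; median 0.08, corrected 0.09, adjusted p = 0.0231, but adjusted p = 0.136 with an estimated correlation), with the desaturase SCD at 1723 ± 15.8 FPKM against 1130.4 ± 3.91 in M4 (n = 2, 0.59 ± 0.03, adjusted p = 2.3e-13) and its regulator SREBF1 at 0.50 ± 0.03, adjusted p = 1.2e-10. TGF-beta targets fell (3 up and 10 down of 20, or 3 and 10 adjusted over the list alone; median -0.22, corrected -0.23, adjusted p = 0.00729, but adjusted p = 0.136 with an estimated correlation), with the matricellular protein CYR61 at 525 ± 3.56 against 1152 ± 19.5 FPKM in M4 (-1.10 ± 0.03, adjusted p = 2.3e-17). Further lists fell and were lost with an estimated correlation: NRF2 targets (1 up and 11 down of 20, or 1 and 11 adjusted over the list alone; median -0.25, corrected -0.21, adjusted p = 7.8e-05, and adjusted p = 0.118 with an estimated correlation), metalloproteinases (3 up and 10 down of 17, or 3 and 10 adjusted over the list alone; -0.24, -0.28, 0.00563 and 0.136), epithelial to mesenchymal transition (1 up and 8 down of 11, or 1 and 8 adjusted over the list alone; -0.20, -0.26, 0.00563 and 0.128) and endoplasmic reticulum chaperones (2 up and 12 down of 20, or 3 and 14 adjusted over the list alone; -0.15, -0.15, 0.00391 and 0.136). In the same order of values, G2 and mitosis (4 up and 18 down of 30, or 4 and 19 adjusted over the list alone) gave -0.16, -0.14, 0.000824 and 0.218, MYC targets (1 up and 14 down of 22, or 1 and 14 adjusted over the list alone) -0.16, -0.14, 0.00069 and 0.107, S phase (0 up and 14 down of 26, or 0 and 14 adjusted over the list alone) -0.11, -0.13, 0.00363 and 0.118, and hypoxia (3 up and 13 down of 22, or 3 and 14 adjusted over the list alone) -0.10, -0.10, 0.00155 and 0.118. Oxidative phosphorylation (0 up and 18 down of 25, or 1 and 18 adjusted over the list alone) gave -0.13, -0.07, 0.00116 and 0.155, and autophagy (2 up and 13 down of 23, or 2 and 13 adjusted over the list alone) -0.11, -0.09, 0.0133 and 0.136. After correction, further lists passed against WT. Antigen presentation passed in M6 (adjusted p = 2.2e-05), M10 (0.000128) and M13 (2.5e-05), and epithelial junctions likewise (0.00658, 0.00347 and 0.00679). With the correction and an estimated correlation antigen presentation still passed (adjusted p = 0.0226, 0.0322 and 0.0221 in M6, M10 and M13) and epithelial junctions did not (0.123, 0.11 and 0.121). Endoplasmic reticulum chaperones passed downward in M6 (0.0141) and M13 (0.0123), and not with the correction and an estimated correlation (0.0729 and 0.0721). Also after correction, cytokines passed downward in M10 (0.0381), metalloproteinases upward in M6 (0.0158) and M13 (0.0272), and DNA damage repair downward in M6, M10 and M13 (0.0207, 0.0168 and 0.0138). None of these held with an estimated correlation (0.139, 0.124, 0.156, 0.0849, 0.0788 and 0.0721). Oxidative phosphorylation passed downward with the correction and weights together in M10 (adjusted p = 0.0156) and M13 (0.0344). Not past the threshold for M10 against the other mutants were antigen presentation (4 up and 8 down of 20, or 4 and 8 adjusted over the list alone, adjusted p = 0.437), p53 targets (5 up and 8 down of 18, or 6 and 8 adjusted over the list alone, 0.174), the integrated stress response (6 up and 8 down of 22, or 7 and 9 adjusted over the list alone, 0.492), cholesterol biosynthesis (5 up and 4 down of 21, or 5 and 4 adjusted over the list alone, 0.437), epithelial junctions (8 up and 6 down of 23, or 8 and 6 adjusted over the list alone, 0.453), squamous differentiation (5 up and 5 down of 13, or 5 and 5 adjusted over the list alone, 0.952; median 0.12, mean -0.0021) and DNA damage repair (5 up and 4 down of 20, or 5 and 4 adjusted over the list alone, 0.935). The quality lists stood at 0.52 (mitochondrial) and -0.51 (nuclear) here too.

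Against WT, the median, mean and test of some lists that did not pass differed in sign. Extrinsic apoptosis had medians of -0.31 to -0.23 and means of 0.05 to 0.18 with a negative camera test in all 4 mutants, while fry was upward in M10 (adjusted p = 0.00545) and M13 (0.218). DNA damage repair had a positive median and mean and a negative test in M4, M6 (0.02 and 0.03) and M10 (0.21 and 0.02). The p53 targets had medians of -0.02, -0.0065 and -0.03 in M6, M10 and M13 against means of 0.21, 0.05 and 0.21. Negative medians went with positive means also for lipid synthesis in M6 (-0.02 and 0.36) and intrinsic apoptosis in M10 (-0.02 and 0.29). Except for extrinsic apoptosis, the signs of these medians hung on single WT libraries: the repair medians were 0.40, 0.40 and 0.34 without WT replicate 1 and -0.42, -0.50 and -0.34 without WT replicate 2. For p53 targets they were -0.32, -0.29 and -0.32, and 0.27, 0.28 and 0.26. The lipid median in M6 was 0.04 and -0.20, and the intrinsic apoptosis median in M10 -0.08 and 0.04. With upper quartile scaling the M6 repair median was -0.03.

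FOXD1, a forkhead transcription factor, differed within groups: its FPKM was 14.5 and 36.6 in WT, 2.73 and 33.1 in M4, 0.996 and 1.47 in M6, 0.885 and 0.478 in M10, and 36.2 and 2.36 in M13. It passed in M6 (-3.44 ± 1.22, adjusted p = 0.0326) and M10 (-3.85 ± 1.22, adjusted p = 0.0203) against WT, and not with weights for WT and mutant libraries (adjusted p = 0.467 and 0.409). The M6 call ended also without either M6 library (0.113 and 0.0905) and the M10 call without either M10 library (0.0634 and 0.0817).

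The tests on the WT libraries were chosen after the result was seen, except the test for another cell line. WT libraries differed from the mutants and from each other. In the unweighted fit of all 10 libraries 9563 to 9697 of 13244 genes were called, and 5418 to 5723 with weights. A different cell line is argued against, since 0 genes had an FPKM of 10 or more in both WT libraries and under 0.1 in all mutant libraries. The reverse count was 0 too, but mutant-like RNA in WT replicate 1 could give that by itself. Genes of the Y chromosome, XIST and TSIX did not enter these counts. WT replicate 1 as a mixture of RNA like WT replicate 2 with RNA like the mutants stays open: the mutant-like share of 318 genes ran from 0.0448 to 0.312 (10th to 90th percentile, a ratio of 6.97), but the spread a mixture would give was not measured in these genes near the floor of WT replicate 2. A GC and length trend accounts for 49.6% of the variance in WT replicate 2, but as the whole cause of the hypoxia and interferon increases it is argued against, since their medians stayed at 1.26 or more after correction. Lower RNA integrity or less nuclear RNA in the WT libraries may add to the pattern: WT replicate 2, farther from the mutants, had the mitochondrial list higher by 0.644 and the nuclear RNAs at -0.356 relative to WT replicate 1. All WT libraries could also share a batch, which the labels do not give and which cannot be told apart from the transfection, so an effect of wild-type against mutant caspase-8 remains a hypothesis.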
